A study of Mus musculus with 4 samples.

How the data were processed

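Small RNA was profiled in 4 samples of the mouse line CGR8, 2 labelled as day 0 ESCs and 2 as day 8 EBs. Per the labels' protocols, small RNA was extracted with a microRNA isolation kit, about 100 ng entered each library of the Ion Total RNA-Seq kit, libraries were amplified by PCR, and sequencing used 316 chips on an Ion Torrent PGM. No molecular identifiers are described, so PCR copies were counted as reads. The aligner, the counter, the genome build and the microRNA database release are not given in the sources used here.

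The deposited table held 1 row for each of 626 microRNA genes, named by precursor. Original counts per replicate were deposited by the authors as whole numbers, per the file headers, with no normalization. The mean of the replicates was given by the authors too, and was treated as an estimated count that need not be whole. The normalized signal, per the file headers, held the same set of values in all 4 columns, which is what quantile normalization over the samples gives. The authors' transformed values equalled log2 of the normalized ones. The fold computed on transformed values, per the file headers, was treated as a score, since it equalled the ratio of 2 mean log2 values and is no fold change. The table also held the authors' p-values, from a test that is not given in the sources used here. Replicates were matched to columns by their stated order number, and groups were taken from the labels.

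The original counts were out of register with the rest of the table. The 4 original count cells of mir-664 were blank, and from that row on, over 170 rows, the counts followed the normalized values of the row above. The rank correlation between original counts and normalized values in these rows was 0.355 to 0.541 as deposited and 0.995 to 0.998 after the counts were moved up by 1 row. In 8 families with several gene copies among these rows, the median range over copies was 4.08 on the log2 scale as deposited and 0.11 after the move. The move left mir-99b, at the displaced end, without counts. All 7280 candidate sets of its 4 counts were tried, and 1 of them (1300, 1306, 70 and 74) gave every one of the 626 normalized values when quantile normalization was repeated. Those counts were used, so the values of mir-99b were reconstructed and not read from the table.

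Depth was taken as the total microRNA count, 557250 and 557643 for the ESC columns and 139104 and 139360 for the EB columns. The columns of each group were compared by a chi-square test over entries with at least 10 counts in the pair, 402 for the ESCs and 344 for the EBs, against 1000 simulated pairs of independent libraries. Both pairs differed by less than counting error allows, so the mean of the columns was used as 1 sample per group.

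The design fixed before the data were examined was edgeR's quasi-likelihood test on all 4 columns, with camera for the lists and an exact permutation test for shares. It was kept on record and edgeR (4.0.16) was run, but its adjusted p-values rest on a spread smaller than counting error, so it is not the main result. In its place, and chosen after the data were seen, an entry was counted as higher or lower when the scaled counts of both libraries differed at least 2-fold, and a list was placed by the percentile of its median log2 fold among 10000 random lists of the same size matched on mean CPM in 10 bins. A list was counted as standing apart outside the percentiles 2.5 and 97.5. Folds were computed from mean counts after TMM scaling over the entries kept by filterByExpr (minimum count 10, minimum total 15), with exact conditional binomial intervals at 95%. Intervals of shares are exact Clopper-Pearson intervals. Where a group had 0 counts and the other was above a floor of 3 counts, the 0 was set to 3. No fold was given when both groups were at or under the floor, or when the floor would have turned the direction.

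The named microRNAs followed a rule fixed before the data were examined: the 10 most abundant entries of each group, the 8 highest and 8 lowest folds among entries with a mean CPM of at least 50 and both EB columns on the same side of both ESC columns, up to 4 of the most abundant members of each list, and the 4 microRNAs of the published study. The rule also asked for an adjusted p under 0.05, which was dropped with the test. It named 83 entries. The 18 lists were fixed before the data were examined, and 10 more groups were chosen after the values were seen. Genes and positions were taken from GENCODE release 21 for mouse (GRCm38), to which 591 entries were matched by name and 35 were not. Hairpin similarity was measured as the fewest mismatches over windows of 20 bases.

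Calculations used R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fold and list calculations were tested on simulated counts for the same 367 entries, 200 of them changed. These counts held counting error only, which is what the intervals assume, and the library totals were supplied. The simulation therefore checks the arithmetic, and tests neither TMM scaling nor spread beyond counting error. The intervals held the true fold for 95.9% of entries, 89% of entries with a true log2 fold of 1.5 and 87% of those with 3.0 were found at least 2-fold apart, and 7.78% of unchanged entries were too. Of 100 random lists, 5 fell outside the central 95%. The simulated entries varied independently, so this share does not cover lists whose members share a transcript or reads. The alternatives were other scalings (RLE, library totals, upper quartile), other filters, the miR-290 to miR-295 cluster left out, identical rows counted once, single columns left out, the replicate number as a block, limma-voom and DESeq2. The authors' quantile-normalized values, the counts in their rows as deposited, the summing of copies of the same microRNA and the Sfmbt2 list cut to entries placed in that gene were added after the data were seen.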

Results

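MicroRNA abundance was measured in mouse embryonic stem cells (ESCs) and in embryoid bodies (EBs) made from them, by small RNA sequencing on an Ion Torrent PGM. The cells were of CGR8, an embryonic stem cell line that grows without feeder cells and is kept undifferentiated by leukemia inhibitory factor (LIF). The day 0 samples were ESCs grown with LIF at 100 U/ml in 10% serum. The day 8 samples were EBs, aggregates in which stem cells differentiate without LIF, grown for 2 days in hanging drops of 1000 cells and for 6 more days in suspension in 20% serum. The labels name 2 samples in each group. The comparison asks which microRNAs differ in abundance between the stem cells and the day 8 aggregates.

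The table held 626 microRNA gene entries, named by precursor. The total microRNA count was 557250 in ESC replicate 1, 557643 in ESC replicate 2, 139104 in EB replicate 1 and 139360 in EB replicate 2. The EB samples were therefore 4.0 times shallower. A floor of 3 counts corresponded to a CPM (count scaled to a common library total) of 5.38 in ESC replicate 1 and of 21.6 in EB replicate 1. The replicates of each group differed by less than the sampling noise. The chi-square per degree of freedom was 0.235 for the ESC pair and 0.284 for the EB pair, whereas 1000 simulated pairs of independent libraries gave 0.791 to 1.27 and 0.772 to 1.27. Each pair was therefore counted as 1 sample, by its mean. The comparison thus rested on 1 library per group, had no replicate check and gave no p-value. Fold values below carry exact 95% intervals that cover counting error only, so they compare these libraries, not the conditions. The intervals also take the scaling between the libraries as exact, and other scalings moved some folds beyond them.

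Of 367 entries with enough counts to be measured, 123 were at least 2-fold higher in the EB library, 111 were at least 2-fold lower and 133 lay under 2-fold either way. The counting interval excluded no difference for 117 of the 123 and for 102 of the 111. The filter works on CPM, so it admitted entries at fewer counts in the shallower EB library. With no filter, 115 entries were at least 2-fold higher and 134 at least 2-fold lower. Which direction held more entries therefore depended on the filter. The measured entries held 99.9% of the ESC counts and 99.8% of the EB counts. In the ESC library mir-293 alone took 24.9% of all counts, followed by mir-292a with 11.4%, mir-291a with 7.41% and mir-294 with 5.26%. The most abundant entry of the EB library was mir-294 with 26.3%, followed by mir-293 with 13.8%, mir-292a with 8.62%, mir-302d with 3.76% and mir-18a with 3.47%. The other ESC entries among the top 10 were mir-16-2, mir-16-1, mir-182, mir-295, mir-290a and mir-191, and those of the EB library were mir-302b, mir-17, mir-20b, mir-20a and mir-19b-1. The top 10 took 62.8% of the ESC library and 64.8% of the EB library. Scaling by the trimmed mean of M-values (TMM) set every EB to ESC log2 fold 0.28 lower than library totals would. The median log2 fold of measured entries was 0.07 with TMM, 0.35 with library totals and -0.19 in the authors' deposited quantile-normalized values.

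**Figure D1:**
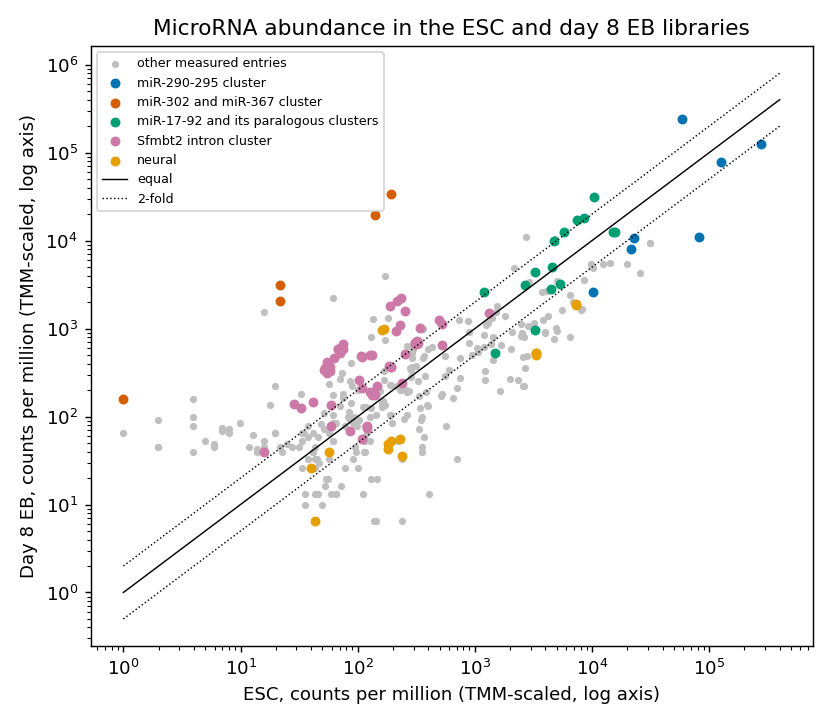
Each point is 1 of the 367 measured entries, with its TMM-scaled CPM in the ESC library on the horizontal log axis and in the day 8 EB library on the vertical log axis (values under 1 drawn at 1), and colours mark 5 fixed lists. The solid line marks equal abundance and the dotted lines 2-fold differences; the miR-302 and miR-367 entries lie far above the lines, and 11 of the 15 neural entries lie below them.

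The miR-302 and miR-367 cluster, known from pluripotent and epiblast-stage cells, was scarce in the ESC library and abundant in the EB library. All 5 measured members were at least 2-fold higher in the EB library. Together they took 0.0341% of ESC counts (exact binomial interval 0.0294 to 0.0393) and 6.53% of EB counts (6.41 to 6.67), and their TMM-scaled sum was 158-fold higher (136 to 183). The entry mir-302d was 178-fold higher (145 to 219), with a mean of 97 counts in the ESC library and 5236 in the EB library. The differences were 141-fold (111 to 181) for mir-302b, 146-fold (80.7 to 294) for mir-302a and 93.6-fold (51.6 to 189) for mir-302c. The fifth member, mir-367, had 0 counts in the ESC library and 24 in the EB library, and was named for its place in the cluster after its values were seen. The cluster lies on chromosome 3 at 127545228 to 127545807 (GRCm38), with no annotated host gene on its own strand. Genes on the other strand were not searched. The list's median log2 fold of 7.14 stood at the 100th percentile of 10000 random lists matched on abundance.

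The miR-290 to miR-295 cluster, the main microRNA cluster of mouse ESCs, took 53.9% of ESC counts (53.8 to 54.1) and 52.3% of EB counts (52.0 to 52.6), but its members went in opposite directions. Of 7 measured members, 5 were at least 2-fold lower in the EB library, mir-292a was 1.60-fold lower (1.57 to 1.63) and mir-294 was 4.10-fold higher (4.04 to 4.17). The lowest was mir-291a, 7.44-fold lower (7.08 to 7.81), and mir-293 was 2.19-fold lower (2.16 to 2.23). The log2 folds of mir-290a and mir-295 were -1.42 (-1.51 to -1.33) and -1.10 (-1.18 to -1.03). Under library totals the log2 folds of mir-293 and mir-295 were -0.85 and -0.82, under 2-fold, and mir-295 was at -0.85 in the quantile-normalized values. The log2 fold of mir-294 was 2.04 (2.01 to 2.06) with TMM, 2.32 under library totals and 2.34 in the quantile-normalized values, so its size depended on scaling. The mapped members lie within 3218626 to 3220841 on chromosome 7 (GRCm38), where mir-294 spans 3220641 to 3220724. The hairpins of mir-291a and mir-291b each share a 20-base stretch with that of mir-294 at 2 mismatches, so reads of these entries can be hard to tell apart.

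**Figure D2:**
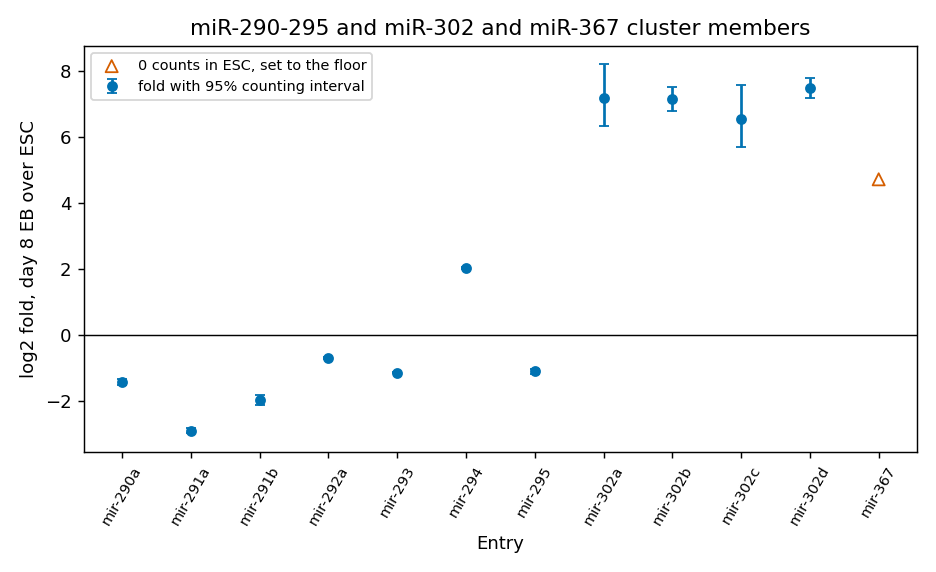
Log2 folds (EB over ESC, TMM-scaled) of the measured members of the miR-290 to miR-295 and miR-302 and miR-367 clusters, as points with exact 95% counting intervals; the open triangle marks mir-367, whose 0 ESC counts were set to a floor of 3. Within the first cluster only mir-294 lies above 0, at 2.04, whereas the miR-302 members lie between 6.55 and 7.47.

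The miR-17-92 cluster and the paralogous miR-106a and miR-106b clusters, linked to proliferation, took 8.50% of ESC counts and 15.1% of EB counts. Of 15 measured entries, 6 were at least 2-fold higher in the EB library, 2 were at least 2-fold lower and 7 lay under 2-fold; in the quantile-normalized values 7 were higher. The most abundant in the EB library, mir-18a, was 3.01-fold higher (2.89 to 3.13), mir-20b 2.34-fold (2.23 to 2.46), mir-20a 2.21-fold (2.08 to 2.34) and mir-17 2.11-fold higher (2.01 to 2.21). The entries mir-25 and mir-363, named after their values were seen, were the lower ones, with log2 folds of -1.77 (-2.03 to -1.53) and -1.48 (-1.83 to -1.15). The log2 folds of the copies mir-19b-1 and mir-19b-2 were -0.32 and -0.28, and 0.29 and 0.08 in the quantile-normalized values, so their direction depended on scaling. The list's median log2 fold of 0.23 was at percentile 99.3 of matched random lists. It was at percentile 97.0 when copies of the same microRNA were summed. Entries of miR-17-92 map to chromosome 14 within Mir17hg, and those of the miR-106b cluster to chromosome 5 within Mcm7.

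The let-7 family, whose mature forms accumulate in differentiated cells, was scarce in both libraries, with 0.182% of ESC counts (0.171 to 0.193) and 0.146% of EB counts (0.126 to 0.167). Of 10 measured entries, none was 2-fold higher, 8 lay under 2-fold and let-7c-1 and let-7c-2 were at least 2-fold lower, at 58 counts in the ESC library and 8 and 6 in the EB library. The log2 folds of let-7g and let-7d were both -0.97, with intervals of -1.46 to -0.50 and -1.63 to -0.37, and those of let-7e and let-7a-2 had intervals that included 0. The number at least 2-fold lower depended on scaling, with 1 under library totals and 5 in the quantile-normalized values. The median log2 fold of -0.41 was at percentile 13.9. The miR-99, miR-100 and miR-125 families, often transcribed with let-7, were lower in the EB library in all 4 measured entries. Their sum was 6.12-fold lower (5.31 to 7.08). The log2 folds were -2.64 (-2.92 to -2.37) for mir-125a, -2.46 (-2.82 to -2.12) for mir-99b and -2.96 for mir-125b-2. The median of -2.80 was at percentile 0.295, and at 2.94 with copies summed.

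Of the 6 lists of lineage-enriched microRNAs fixed before the data were examined, the neural, endoderm and mesenchymal lists had lower medians in the EB library. The epithelial list and the endothelial and blood list had higher medians, but their summed counts were 2.74-fold (2.63 to 2.86) and 1.29-fold lower (1.18 to 1.40) after scaling. Muscle had no measured entry. Of 15 measured neural entries, 11 were at least 2-fold lower, 2 at least 2-fold higher and 2 under 2-fold, with a median log2 fold of -2.0 at percentile 0.02 (0.31 with copies summed). The copies mir-124-1 and mir-124-2, of the neuron-enriched miR-124, were 6.31-fold (5.05 to 7.99) and 6.25-fold lower (5.01 to 7.90), and mir-7a-1 and mir-7a-2 were 3.84-fold (3.41 to 4.34) and 3.99-fold lower (3.53 to 4.51). The higher entries were both copies of miR-218, a microRNA known from motor neurons and also made from the Slit2 and Slit3 genes, at log2 folds of 2.55 and 2.59; they were named after their values were seen. The list took 2.37% of ESC counts and 0.837% of EB counts. The copies of miR-124, of miR-7a and of miR-218 had nearly equal folds and were not taken as separate evidence. With all numbered copies summed, the 15 measured entries came to 8 microRNAs, so the counts of entries above weigh copies singly.

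All 3 measured endoderm and liver entries were at least 2-fold lower: mir-192 by 3.99-fold (2.65 to 6.25), and mir-194-1 and mir-194-2 at 2 and 3 EB counts. The median of -2.73 was at percentile 1.16, and with copies summed only 2 microRNAs were left, too few for a percentile. Of 10 measured mesenchymal, smooth muscle and Hox-linked entries, 6 were at least 2-fold lower and 4 under 2-fold, with a median of -1.45 at percentile 1.22 (2.01 with copies summed). The smooth muscle pair mir-145a and mir-143 was 7.44-fold (5.41 to 10.3) and 7.32-fold lower (4.13 to 14.3), mir-21a was 2.32-fold lower (2.15 to 2.49) but under 2-fold with library totals (log2 fold -0.93) and in the quantile-normalized values (-0.69), and the interval of mir-196a-1 included no difference. So did those of mir-10a and mir-199a-2, 2 of the 6 lower entries, named after their values were seen. Cardiac and skeletal muscle entries were near the floor, with 20 counts in the ESC library and 7 in the EB library over the whole list. None of them was measured, and a difference was not detectable at this depth (ratio of sums 1.15, interval 0.411 to 2.84).

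**Figure D3:**
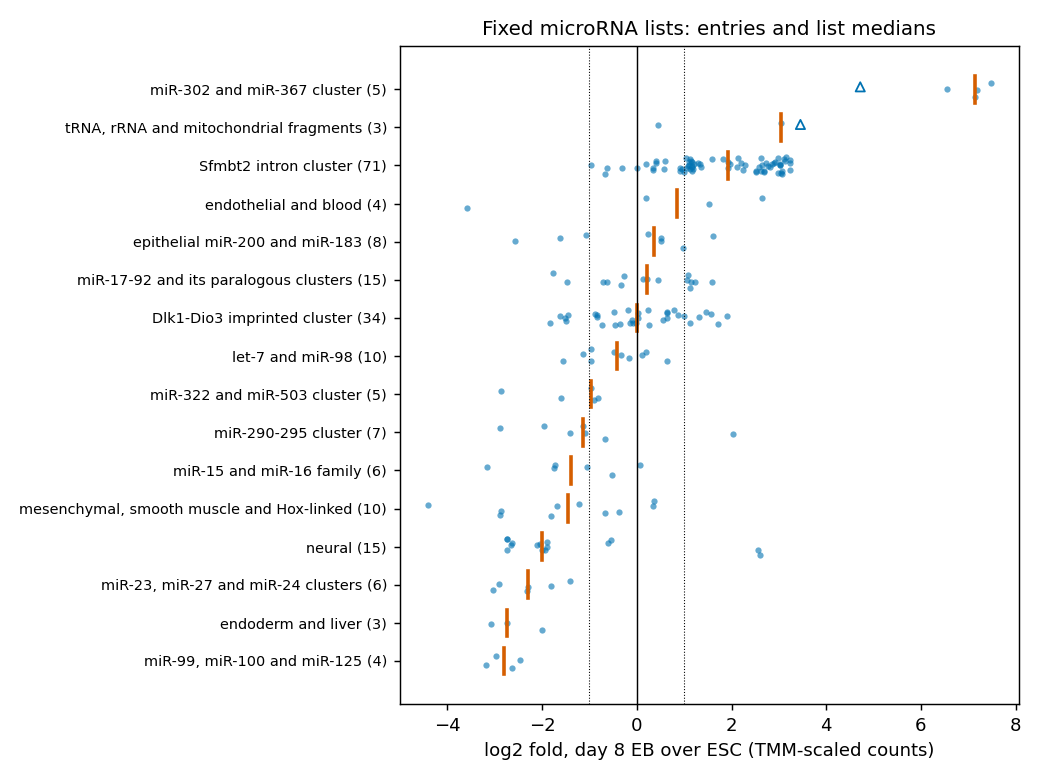
Log2 folds (EB over ESC, TMM-scaled) of the measured entries of the 16 fixed lists with at least 3 of them, with the number measured in parentheses; points are entries (jittered vertically), open triangles entries whose 0 ESC counts were set to the floor, bars list medians and dotted lines 2-fold differences. The miR-302 and miR-367 median lies at 7.14 and the miR-99, miR-100 and miR-125 median at -2.80, while the Dlk1-Dio3 median lies at 0.00.

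Epithelial microRNAs differed in direction by family after TMM scaling, and the difference between the families was not tested. The miR-183 family members mir-182, mir-183 and mir-96 were 5.93-fold (5.48 to 6.42), 2.10-fold (1.94 to 2.27) and 3.06-fold lower (2.63 to 3.57) in the EB library, although mir-183 and mir-96 lay under 2-fold in the quantile-normalized values, at log2 folds of -0.60 and -0.68, and mir-183 also with library totals, at -0.78. In the miR-200 family, which maintains epithelial identity, mir-200c was 1.17-fold higher (1.02 to 1.35). With TMM the single entry at least 2-fold higher was mir-429, named after its values were seen, at a log2 fold of 1.61 (1.29 to 1.93). The others, mir-141, mir-200a and mir-200b, also named after their values were seen, were at 0.98, 0.52 and 0.51. In the quantile-normalized values mir-200a was at -0.15. With library totals 2 entries of the list were at least 2-fold higher, and 3 in the quantile-normalized values, among them mir-200c at 1.02. The whole list of 8 had a median of 0.37 at percentile 73.0. Among endothelial and blood entries, mir-142a, enriched in blood cells, was 6.28-fold higher (4.61 to 8.61) and mir-155 was 2.87-fold higher (1.65 to 4.96) on 31 and 27 counts. The lymphoid microRNA mir-150 was 11.95-fold lower (8.51 to 17.3), and mir-126a, made from the endothelial gene Egfl7, was 1.14-fold higher (1.03 to 1.27). The median of these 4 was 0.85 at percentile 84.6.

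The list of microRNAs named like those of the rodent repeat cluster in an intron of Sfmbt2 was higher in the EB library as a group. Of 71 measured entries, 55 were at least 2-fold higher (1 with an interval that included no difference, mir-669k, named after its values were seen), none was 2-fold lower and 16 lay under 2-fold; 41 were higher and 1 lower in the quantile-normalized values. The list took 1.14% of ESC counts and 4.45% of EB counts, and its TMM-scaled sum was 3.22-fold higher (3.11 to 3.34). The entries mir-467c, mir-467d and mir-467e were 9.46-fold (7.55 to 11.8), 9.44-fold (7.47 to 12.1) and 9.43-fold higher (7.63 to 11.7), whereas mir-669b lay at 1.14-fold (0.977 to 1.32). Whether reads of these similarly named entries can be told apart was not measured, so their nearly equal folds were not taken as separate evidence. The 55 higher entries of the list are part of the 123 in the whole comparison. The median log2 fold of 1.92 was at the 100th percentile, and was 2.10 over the 33 microRNAs left when copies were summed. Summing joined numbered copies only, so mir-467c, mir-467d and mir-467e stayed apart and may still share reads. In the annotation, 70 of the 81 entries lie in Sfmbt2, at 10466663 to 10518279 on chromosome 2, 8 lie elsewhere and 3 were not placed. Of the 65 measured entries placed in the gene, 51 were at least 2-fold higher, and their sum was 3.26-fold higher (3.15 to 3.38).

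The imprinted Dlk1-Dio3 cluster on chromosome 12 (109563692 to 109743795) had entries in both directions after TMM scaling. Of 34 measured entries, 6 were at least 2-fold higher, 5 at least 2-fold lower (2 with intervals that included no difference, mir-381 and mir-487b, named after their values were seen) and 23 under 2-fold, with a median of 0.00 at percentile 28.4. Library totals gave 9 higher and 5 lower, and the quantile-normalized values 5 and 8, with a median of -0.29. The cluster's TMM-scaled sum was 0.989-fold (0.931 to 1.05). Its share was 0.840% of ESC counts (0.816 to 0.864) and 1.01% of EB counts (0.959 to 1.07), so the reading depended on scaling. Single entries differed: mir-134 was 1.72-fold higher (1.43 to 2.05), and over 2-fold with library totals and in the quantile-normalized values (log2 folds 1.06 and 1.58), and mir-541 was 1.78-fold lower (1.47 to 2.17), while the log2 folds of mir-409 and mir-379 were -0.48 and -0.36. In the X-linked miR-322 and miR-503 cluster, 2 of 5 measured entries were at least 2-fold lower, mir-351 by 7.29-fold (3.04 to 22.9) and mir-542 by 3.04-fold (2.03 to 4.74). The entries mir-503 and mir-322 were 1.94-fold (1.54 to 2.48) and 1.88-fold lower (1.47 to 2.42), and the median of -0.96 was at percentile 9.05. In the quantile-normalized values all 5 were at least 2-fold lower.

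All 6 entries of the miR-23, miR-27 and miR-24 clusters were at least 2-fold lower in the EB library, and their sum was 4.56-fold lower (4.29 to 4.84). The entry mir-23b was 2.67-fold lower (2.40 to 2.98) but under 2-fold in the quantile-normalized values, at a log2 fold of -0.73, and mir-24-1 and mir-24-2 were 4.96-fold (4.36 to 5.66) and 4.93-fold lower (4.35 to 5.62). The median log2 fold of -2.31 was at percentile 0.69, and at 2.56 with copies summed. In the miR-15 and miR-16 family, 4 of 6 measured entries were at least 2-fold lower (3 with library totals), with mir-15a 8.91-fold lower (6.51 to 12.5) and mir-16-2 3.34-fold lower (3.17 to 3.53). The log2 fold of mir-15b was -0.52, and 0.07 in the quantile-normalized values. The median of -1.39 was at percentile 10.1.

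The published study of these samples followed up mir-191, mir-16-1, mir-23a and mir-421, so this list was chosen on the same libraries and is not independent evidence of its direction. In the EB library mir-191 was 3.64-fold lower (3.39 to 3.91), mir-16-1 3.31-fold lower (3.14 to 3.50) and mir-23a 8.19-fold lower (6.83 to 9.89). The remaining one, mir-421, was 36.2-fold higher (25.0 to 54.1), on 31 ESC counts and 341 EB counts. The copies mir-16-1 and mir-16-2 had nearly equal mean counts, 15702.5 and 15867.5 in the ESC library and 1441.5 and 1442.5 in the EB library. The difference was therefore not assigned to the mir-16-1 gene alone. In GRCm38, mir-191 lies on chromosome 9 at 108568319 to 108568392, mir-16-1 on chromosome 14 at 61631880 to 61631972 within Dleu2, mir-23a on chromosome 8 at 84208518 to 84208592 and mir-421 on chromosome X at 103572921 to 103572996 in an intron of the noncoding gene Ftx.

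Among measured entries with a mean of at least 50 CPM, the 8 with the highest EB to ESC ratios, with 0 counts set to 3, were mir-302d, mir-302a, mir-302b, mir-489, mir-302c, mir-743b, mir-421 and mir-880. The entry mir-489, in an intron of Calcr on chromosome 6, was 98.3-fold higher (49.1 to 230.3) on 8 ESC and 239 EB counts. The ratio of mir-743b was 39.5 (9.80 to 345) on 2 ESC counts. With 0 ESC counts and 25 EB counts, mir-880 was 27.4-fold higher against a floor of 3 counts, with an exact lower limit of 20.7 on the counts. The next entry, mir-367, had 24 EB counts. The 8 lowest were mir-221, mir-193a, mir-211, mir-181d, mir-10b, mir-150, mir-674 and mir-125b-1. Their folds were large but several rested on very few EB counts. The entry mir-221 had 120 ESC counts and 1 EB count, a log2 fold of -5.19 (-10.50 to -2.68), and mir-193a had 206 and 2 counts, a log2 fold of -4.97 (-8.02 to -3.10). The log2 folds of mir-211, which lies in an intron of Trpm1, and of mir-10b, which lies in the Hoxd cluster, were -4.47 (-9.79 to -1.95) and -4.41 (-9.74 to -1.89), each on 1 EB count. The entry mir-181d was 21.6-fold lower (9.19 to 67.1) on 356 and 5 counts, mir-674 was 11.7-fold lower (8.34 to 17.0) on 1311 and 34 counts, and mir-125b-1 was 9.04-fold lower (4.08 to 25.0).

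Entries known or suspected to be fragments of transfer, ribosomal or mitochondrial RNA, a sign of RNA degradation, took 0.0101% of ESC counts (0.00774 to 0.0132) and 0.0269% of EB counts (0.0193 to 0.0375). Their TMM-scaled sum was 2.18-fold higher in the EB library (1.42 to 3.36), and their median was at percentile 93.6. Of 3 measured, mir-712 was 8.23-fold higher (2.37 to 35.9) on 4 and 10 counts, mir-2137 was 10.97-fold higher against the floor on 0 and 10 counts (exact lower limit 7.37), and mir-690 had an interval that included no difference. Both mir-712 and mir-2137 passed the filter through their EB counts, whereas mir-696, with 7 ESC and 0 EB counts, was not measured. The direction of the measured entries and their percentile are therefore partly set by the filter. Of the 16 lists with at least 3 measured entries, 8 had medians outside the central 95% of matched random lists. When copies of the same microRNA were summed, 4 did: miR-302 and miR-367, neural, mesenchymal and Sfmbt2. Random lists were drawn entry by entry, whereas members of a genomic cluster or family can share a transcript or reads. The percentiles can therefore overstate how far such lists stand apart. A percentile also places a median among entries of like abundance, not against no difference. The miR-290 to miR-295 median of -1.13 was at percentile 37.4, and the Dlk1-Dio3 median of 0.00 at 28.4. The entries drawn from included the 55 higher ones of the Sfmbt2 list. In the authors' deposited table, 442 of 468 entries with an adjusted p had one under 0.05, and 291 of these also had a normalized fold of at least 2 either way. The test behind those p-values is not given in the sources used here.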

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

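The 2-fold rule, the random lists, the quantile-normalized values, the rows as deposited, the summing of copies and the cut Sfmbt2 list were chosen after the data were seen. The counts of entries at least 2-fold higher (123) and lower (111) stayed within 1.5 times of these values under every alternative run, from 90 to 141 higher and from 96 to 134 lower; summing copies gave 90 and 97 over 301 microRNAs. The number of lists standing apart was 8, and 7 to 9 under the alternatives other than summing copies, which gave 4: the lists of miR-17-92, of miR-99, miR-100 and miR-125, of endoderm and of miR-23, miR-27 and miR-24 were lost, with fewer members by construction. With the Sfmbt2 list cut to entries placed in that gene it stayed at 8. Of 1219 named and list values compared, 1073 stayed within their interval or the spread of their list and 145 moved beyond it. Most moves came with a change of scaling: 33 with library totals, 40 with upper quartile and 40 with the quantile-normalized values, where 62, 55 and 52 stayed. Leaving out a single column moved only 0 to 3 values per run, since the columns of a group are nearly alike. The pooled total therefore understates how far values depended on scaling. Folds under 2-fold and medians of lists not standing apart changed sign 21 times, in 8 results. Of the other values 1 reversed: mir-674 had a log2 fold of 0.40 with counts in the rows as deposited, by the displacement. With the most abundant entry of each library left out, mir-293 of the ESC and mir-294 of the EB library, the miR-290 to miR-295 cluster took 38.6% and 35.3% of the ESC and EB libraries, the miR-302 and miR-367 cluster 0.0454% and 8.86%, miR-17-92 and its paralogs 11.3% and 20.5%, and let-7 0.242% and 0.198%, by construction.

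With the columns taken as replicates, edgeR called 300 of 367 entries at an adjusted p under 0.05, 156 higher and 144 lower, DESeq2 268, limma-voom 331, and edgeR with 1 column left out 265 to 286, the lone column being assumed to vary like the other group. These counts do not measure differences between cultures. The replicate block also gave 300; columns with the same number had deviations correlated at 0.17, and with 2 pairs and no pairing in the labels the number is only a name. Not run were camera with either correlation, fry and the list tests with a block, for want of residual spread among samples at 1 library per group, the permutation test of shares for the same reason, and the pseudocounts and filter planned for normalized values, which the counts made needless. Depth limits entries with few EB counts: the floor of 3 counts is a CPM of 21.6 in EB replicate 1.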

Other observations

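All tests in this part were chosen after the result was seen, except the thinning and the other totals for the neural list; the microRNA groups of the next paragraphs were also picked after their values were seen, so their counts are descriptions and not evidence of enrichment. Several small genomic groups took a smaller share of the ESC library than of the EB library. The X-linked neighbours mir-374b and mir-421, both in an intron of Ftx, had log2 folds of 4.53 (4.20 to 4.87) and 5.18 (4.65 to 5.76). Their list took 0.0210% of ESC counts and 0.681% of EB counts. The pair mir-489 and mir-653, both in an intron of Calcr, rested on 9 ESC counts and 246 EB counts together, 89.9-fold higher after scaling (46.6 to 199). A cluster on chromosome X at 66777256 to 66835842, near Fmr1, had 12 measured entries, and each was at least 2-fold higher in the EB library. Its sum was 13.4-fold higher (9.79 to 18.5) on 51 ESC and 207 EB counts, and members such as mir-741, mir-743b and mir-880 had 10, 2 and 0 ESC counts. With so few ESC counts, entries passed the filter largely through their EB counts, so the shared direction is partly set by the filter.

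Other families were lower or divided. All 6 entries of miR-30 were at least 2-fold lower in the EB library, with a sum 3.53-fold lower (3.28 to 3.80), although mir-30a lay under 2-fold with library totals and in the quantile-normalized values (-0.84 and -0.40). The neighbours mir-181c and mir-181d, in an intron of Nanos3, had log2 folds of -3.06 (-3.63 to -2.53) and -4.44. Of the p53-linked miR-34 family, mir-34a was lower, at -1.27 (-1.40 to -1.14; -0.98 with library totals and -0.62 in the quantile-normalized values), whereas mir-34b, mir-34c and the related mir-449a were higher, at 2.24, 2.12 and 4.30, the last on 2 ESC counts. The seed relatives mir-152 and mir-148b had log2 folds of 2.85 (2.48 to 3.21) and -1.40 (-2.23 to -0.58), with mir-148a at -0.80 (-1.25 in the quantile-normalized values). The neighbours mir-221 and mir-222 on chromosome X, usually transcribed together, differed, at -5.19 on 1 EB count and -0.06 (-0.88 to 0.70). All 4 miR-29 entries lay under 2-fold. Of miR-130 and miR-301, mir-130a and mir-301a were at least 2-fold higher, at 1.10 and 1.16, and the other 2 lay under 2-fold.

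The columns of each group agreed more closely than counting error. The chi-square per degree of freedom of the ESC columns was 0.235, below the lowest of 1000 simulated independent pairs (0.791), which argues against separately sequenced libraries. One set of reads mapped again with multi-copy reads placed at random would leave entries with 1 copy equal, but 153 of 168 such entries with at least 100 counts differed between the ESC columns. Where the ESC columns differed, the difference was an even number in 281 of 364 entries (77.2%), against 51.5% at most in the simulations, while 54.0% of counts in the first ESC column were even, so counting in steps of 2 does not account for it. How the columns were made remains open, and no biological explanation was tested.

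Within the miR-290 to miR-295 cluster, mir-294 was higher in the EB library and its 6 measured neighbours were lower. Its ratio to the other members was 0.108 in the ESC library and 1.01 in the EB library, a 9.34-fold difference (9.16 to 9.52), which no scaling between libraries can produce. If reads of the similar mir-291a and mir-291b assigned to mir-294 were the only cause, the sum of the 3 entries should not be higher. Its log2 fold was 0.75 (0.73 to 0.76), which argues against such reads as the whole cause. Whether they account for part of the difference between mir-294 and mir-291a cannot be told from the sum. A preparation or batch difference between the libraries cannot be told apart from the day of culture, since there was 1 independent library per group. No biological explanation was tested.

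The neural, endoderm and mesenchymal lists were lower in the EB library than in the stem cell library, neural by the most extreme percentile. Thinning the ESC counts to the EB total 100 times (0 counts set to 0.5) left the neural median log2 fold at -1.84 or lower. Thinning lowers the counts and the library total alike, so it adds counting noise only and leaves the expected fold as it was. Such noise in the ESC counts did not bring this median under 2-fold, and other effects of depth were not tested. The mesenchymal median ranged from -1.78 to -0.28, which leaves depth open for that list. With totals that left out the miR-290 to miR-295, miR-302 and miR-17-92 lists, which took 62.5% of the ESC and 73.9% of the EB library, the neural median was -1.19 (-1.60 to -0.93 on redrawn counts) and the mesenchymal median -0.64 (-1.53 to -0.00314). Leaving out these lists raises every log2 fold by the same amount, and the TMM folds already had a median of 0.07 over measured entries. The shift therefore cannot decide whether a larger share of abundant clusters accounts for part of either median. As a single factor between libraries, it leaves the lists' percentiles as they were. Library preparation and RNA quality, with 1 independent library per group, and differentiation itself stay open.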
